A study of Mus musculus with 18 samples.

How the data were processed

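RNA sequencing of 18 libraries in 6 groups of 3 was taken from 1 series, with groups assigned from the sample labels. The libraries were strand-specific and made from total RNA of LPS-treated mouse peritoneal macrophages or IC-21 cells, per the labels' protocols. Reads were trimmed with fastp, checked with FastQC, aligned with HISAT2 and counted with featureCounts, per the submitters' processing notes. The deposited values are raw counts of read pairs per gene over exons, made with featureCounts 2.0.3 on reversely stranded pairs with the GENCODE M25 annotation of GRCm38, per the file headers. Each file held 55401 genes. Gene symbols came from the GENCODE M21 tables in the box, matched by identifier without version. A symbol was found for 55141 identifiers and not for 260, and 106 symbols were used by more than 1 identifier. Smim30 was taken to be the gene listed as 2610001J05Rik, from the open reading frame of its main transcript and general knowledge, since the tables do not carry the newer name. The sample of each file was taken from its file name, and the number inside its header differed from that in its name.

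Totals per library ran from 6855245 to 13456857 assigned read pairs. No library had counts on mitochondrial genes, so no mitochondrial share was available as a sign of RNA quality. Ribosomal RNA genes held 0.195 to 2.49% of counts. Replicates of a group differed by more than counting noise, with a chi-square per gene of 1.67 to 5.24 over genes with a summed count of at least 20, and Pearson's r of log2 CPM was 0.9967 or higher. The detection floor was 3 counts in a library.

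The comparisons were Mut against WT, Mut AdSmim30 against Mut AdCtrl, and siSmim30 against siCtrl, each fitted to its own 6 libraries with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr and libraries were scaled by TMM (trimmed mean of M-values). Genes were tested by the robust quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05 within each comparison. Mut AdCtrl against Mut was tested in the same way. It is described in the closing part and used in the report only to judge the sum of effects. Virus, time in culture and part of the series coincide there, so any batch between the parts cannot be separated from them. Interaction terms in models of 12 libraries tested the mutation effect minus the siRNA effect, and the sum of the mutation and virus effects. For 3 libraries against 3 an exact permutation test cannot give a p-value below 0.1, so none was used for single genes. CPM within a comparison was scaled over its 6 libraries, and CPM shown for all groups was scaled to each library's own total, so the values differ slightly.

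A set of 35 gene lists was fixed before the data were examined, as were the comparisons, the tests, most alternative settings and the rule for naming genes. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Members were also adjusted over their list alone. Named genes were Smim30 and 7 cytokine and effector genes in every comparison, the 8 largest rises and falls among called genes with average log2 CPM of at least 2 and groups that did not overlap, up to 4 members of each called list, and the leading genes of overlaps and interaction tests. Clone names and pseudogenes were passed over, and not all genes the rule allows are named. Overlaps of called genes were tested with Fisher's exact test, adjusted over 12 tests, which takes genes as independent and so may overstate the overlaps' certainty. Fold changes were correlated across genes, and libraries were regrouped in all 10 splits of 3 and 3, in all 100 pairs of such splits, or in 50 drawn splits for the interaction tests. Intervals are 95% intervals. For medians and their differences they came from 10000 bootstrap draws of the genes in a set. Such intervals take genes as independent and leave out the spread between libraries, so they may be too narrow.

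Alternative settings chosen before the data were seen were RLE scaling, no composition factor, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of all 18 libraries, replicate number as a block, and leaving out each library in turn. Fits without the ribosomal RNA genes, and with offsets for GC content and exonic length by lowess with a span of 0.3, were added after the data were seen. In the comparison of alternatives, a gene that passed in neither fit counted as unchanged even where its sign differed.

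The tests were run on simulated data with seeded fold changes, 50 genes per fold size. Simulated spread depended on expression level alone, without genes of unusual spread, outlying replicates or correlation between genes. The rates may therefore not hold for the more variable genes. In the simulation of Mut against WT on 12500 genes, 56% of 1.5-fold and 84% of 2-fold changes were recovered, and 4.1% of calls were false. In that of the Smim30 virus on 12701 genes, 76% and 96% were recovered and 2.4% of calls were false. In that of the siRNA on 13576 genes, 74% and 86% were recovered, and 8% of calls were false (13 of 162), above the nominal 5%. Of 1.25-fold changes, 46%, 54% and 42% were recovered in these simulations, in the same order. The median size of the real called changes was 0.31, 0.221 and 0.209 on the log2 scale. For the mutation effect minus the siRNA effect, 14% of 1.25-fold and 54% of 1.5-fold changes were recovered. For the sum of mutation and virus effects, 28% and 48% were. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6. Left out were single transcripts, the sequence of the mutation and reads from the virus, which gene-level counts do not hold, and list tests on the interaction terms, which were added after the data were seen.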

Results

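RNA of mouse macrophages was measured by RNA sequencing in 18 libraries that fell into 6 groups of 3. Every group had received lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages through Toll-like receptor 4, at 5 ng/ml for 6 h. Peritoneal macrophages of wild-type mice (WT) and of mice with a mutated Smim30 gene (Mut) formed the first part. In the second part, Mut macrophages received a control adenovirus (Mut AdCtrl) or a Smim30 overexpression adenovirus (Mut AdSmim30) 6 h after seeding and for 24 h before LPS. The third part used IC-21, an established line of mouse peritoneal macrophages, transfected for 24 h with a control siRNA (siCtrl) or a Smim30 siRNA (siSmim30). Read pairs assigned to genes numbered 9421565, 8531179 and 11198446 in WT replicates 1 to 3, and 7947364, 9020990 and 12246311 in Mut. They numbered 12276683, 10344922 and 10172818 in Mut AdCtrl, and 10393690, 13418135 and 13456857 in Mut AdSmim30. In IC-21 they numbered 6855245, 11990126 and 8642108 with siCtrl, and 8376577, 8788057 and 7482999 with siSmim30. At these depths a count of 3, taken as the detection floor, was worth 0.223 to 0.438 CPM (counts scaled to library size), which covers counting error only. The labels name triplicates and do not say whether they were separate mice or cultures, so the p-values measure only the spread between these samples, which may be technical.

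Gene-level counts of Smim30 were lower with the siRNA, slightly higher with the overexpression virus and not shown to differ in the mutant cells. Smim30, which encodes a small membrane protein, is listed under the clone name 2610001J05Rik (ENSMUSG00000052419.7) on the minus strand of chromosome 6, from 13867735 to 13871518 in GRCm38. Its main transcript has 3 exons, and exon 3 holds the whole coding sequence, 177 bases from 13870535 to 13870711. These bases encode 59 residues and make up 4.68% of the counted exonic length of 3784 bases. In IC-21 cells, Smim30 fell from 21.3 ± 1.21 CPM with siCtrl to 10.8 ± 1.68 CPM with siSmim30 (mean ± SD, n = 3 each), which is 51% of control (log2 fold change -0.97, SE 0.12, edgeR quasi-likelihood adjusted p = 6.17e-08). All 3 siSmim30 libraries, at 8.83 to 12.03 CPM, lay under all 3 siCtrl libraries, at 20.02 to 22.5 CPM. In Mut macrophages with virus, the count of the whole Smim30 gene rose 1.21-fold, from 44.0 ± 1.67 CPM in Mut AdCtrl to 53.2 ± 1.95 CPM in Mut AdSmim30 (n = 3 each; log2 fold change 0.28, SE 0.06, adjusted p = 0.0052). That call was lost without Mut AdCtrl replicate 2 (adjusted p = 0.059), without Mut AdSmim30 replicate 3 (0.113), with DESeq2 (0.0684) and in a fit of all 18 libraries (0.0558), in a range of 0.00245 to 0.113 over all alternatives. Smim30 was at 48.4 ± 3.76 CPM in WT and 48.6 ± 5.41 CPM in Mut (log2 fold change 0.01, SE 0.08, adjusted p = 0.966). The labels do not give the mutated bases, and counts over the whole gene do not show a change within its coding part. A virus that carried the coding sequence alone would add reads over only 4.68% of the counted length. That length covers the whole span of the gene, so the coding part is a larger share of the main transcript with its 3 exons. The labels do not give the insert of the virus, so the size of the overexpression is not known.

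**Figure D1:**
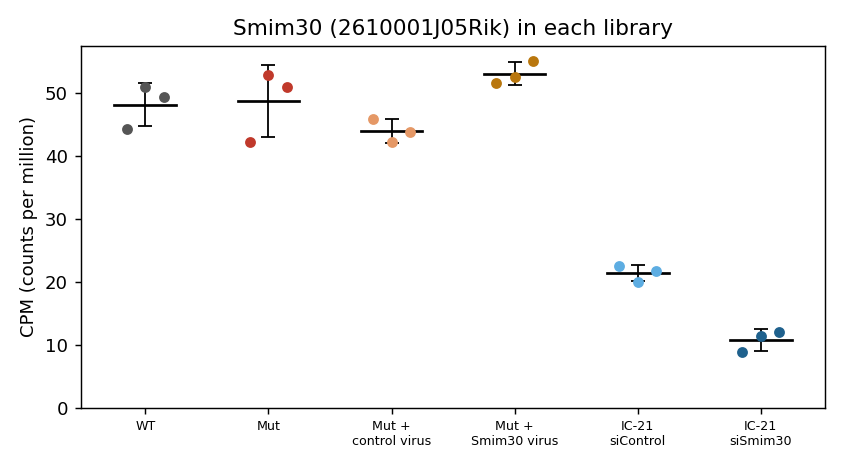
Smim30 (2610001J05Rik) in CPM (y axis, linear) in each of the 18 libraries, by group (x axis); points are libraries, horizontal lines are group means and error bars are 1 SD (n = 3). The siSmim30 libraries lie at 8.83 to 12.03 CPM, below the siCtrl libraries at 20.02 to 22.5 CPM, while WT and Mut overlap.

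The first comparison set LPS-treated Mut macrophages against WT macrophages, to show which transcripts differ between mutant and wild-type cells. Whether the WT mice were littermates of the Mut mice is not known here, so other genetic differences between them could add to these changes. Icosl, the ligand of the T cell costimulator ICOS, had the largest rise by the naming rule, 4.46-fold, from 10.4 ± 0.415 CPM in WT to 46.1 ± 2.46 CPM in Mut (n = 3 each; log2 fold change 2.16, SE 0.10, adjusted p = 1.05e-15). Batf3, a transcription factor of dendritic cells, rose 2.78-fold from 2.34 ± 0.342 to 6.43 ± 1.05 CPM, and Ptx3, a secreted pattern recognition protein, rose 2.52-fold from 4.87 ± 0.215 to 12.5 ± 2.27 CPM. Ltbp1, which binds latent TGF-beta, fell by 1.36 on the log2 scale, from 10.1 ± 0.383 to 3.98 ± 0.764 CPM. Thbd, the thrombin receptor thrombomodulin, fell by 1.24, the complement gene C4b by 0.96 and the transcriptional repressor Bcl6 by 0.90. Of 12500 genes tested, 788 passed at an adjusted p under 0.05, 460 higher and 328 lower in Mut, and 53 of them differed at least 2-fold (37 higher, 16 lower). Without Mut replicate 2 the count was 469. The 3 libraries of one group lay above all 3 of the other for 22.6% of tested genes, where chance gives 10%. Genes of ribosomal RNA held 1.74 to 2.49% of counts in the WT libraries and 0.399 to 1.03% in the Mut libraries.

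Inflammatory cytokines and chemokines were higher in Mut. In the same libraries 2 of 5 dendritic cell markers rose (median 0.30), 1 of 7 B cell markers fell (median -0.50), and 3 of 11 large peritoneal macrophage markers fell and 1 rose (median -0.18). Each of these lists had an adjusted p = 0.182 with an estimated correlation. Of 29 tested members of the list of LPS-induced cytokines and chemokines, 14 rose, 0 fell and 15 did not pass; adjusted over the list alone, 20 rose (median log2 fold change 0.55, camera adjusted p = 1.85e-31; adjusted p = 0.182 with an estimated correlation). The neutrophil attractant Cxcl3 rose 1.64-fold, from 704 ± 34.9 to 1155 ± 41.5 CPM (n = 3 each, adjusted p = 9.57e-12), and its relative Cxcl2 rose 1.37-fold, from 1006 ± 24.0 to 1375 ± 70.1 CPM (adjusted p = 5.75e-08). Tnf rose 1.20-fold, from 1809 ± 54.0 to 2170 ± 153 CPM (adjusted p = 0.000421). Ccl22, a chemokine for T cells, rose 2.49-fold (SE 0.16 on the log2 scale, adjusted p = 1.71e-06). Il1b rose 2.71-fold, from 649 ± 44.7 to 1760 ± 340 CPM (adjusted p = 0.021), and Il6 rose 2.26-fold, from 42.1 ± 0.277 to 96.1 ± 20.2 CPM (adjusted p = 0.0157). The call of Il1b was lost without WT replicate 1 (0.104), WT replicate 2 (0.109), WT replicate 3 (0.0886), Mut replicate 1 (0.0554) or Mut replicate 2 (0.099), and with replicate number as a block (0.143), in a range of 4.92e-22 to 0.143 over all alternatives. That of Il6 was lost without WT replicate 1 (0.12), WT replicate 2 (0.0764), WT replicate 3 (0.0948) or Mut replicate 2 (0.0639), in a range of 3.49e-44 to 0.12. Nos2, the inducible nitric oxide synthase, was at 15.03 ± 3.50 CPM in WT and 31.8 ± 21.1 CPM in Mut and did not pass (adjusted p = 0.483). Il10 and Ifnb1 were below the filter on low counts in all comparisons.

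Interferon-responsive genes and regulators of the LPS response were also higher in Mut, though neither interferon list passed with fry. Of 36 tested genes of the type I interferon response, 10 rose and 0 fell, 23 rose adjusted over the list alone and 26 did not pass over all genes (median 0.55, camera adjusted p = 4.92e-26; adjusted p = 0.31 with an estimated correlation). Cxcl10, an interferon-induced chemokine, rose 1.92-fold, from 36.6 ± 1.93 to 70.8 ± 13.4 CPM (n = 3 each, adjusted p = 0.00261), Rtp4 rose 1.45-fold (adjusted p = 6.62e-05) and Isg20 1.73-fold (adjusted p = 0.00934). Of 14 interferon-inducible GTPases, 2 rose, 0 fell and 12 did not pass, with 11 rising adjusted over the list alone (median 0.64, camera adjusted p = 4.16e-10; adjusted p = 0.348 with an estimated correlation). Of 25 NF-kB subunits and feedback genes, 6 rose, 0 fell and 19 did not pass, with 7 rising adjusted over the list alone (median 0.10, camera adjusted p = 2.47e-05; adjusted p = 0.31 with an estimated correlation). Among them the adhesion molecule Icam1 rose 1.28-fold and the costimulatory receptor Cd40 1.78-fold. Of 21 anti-inflammatory regulators, 8 rose, 1 fell and 12 did not pass, and 10 rose and 3 fell adjusted over the list alone (median 0.24, camera adjusted p = 4.15e-05; adjusted p = 0.214 with an estimated correlation). Socs3, which limits cytokine receptor signalling, rose 1.49-fold and Atf3 rose 1.32-fold, while Bcl6 fell. Of 15 immediate early genes, 5 rose, 0 fell and 10 did not pass, with 5 rising adjusted over the list alone (median 0.12, camera adjusted p = 0.000752; adjusted p = 0.182 with an estimated correlation). Klf6 rose 1.35-fold.

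Shifts were also found in stress response, lysosomal, antioxidant and ribosomal lists between Mut and WT. The lists of oxidative phosphorylation (camera adjusted p = 0.257), glycolysis (0.276) and cholesterol synthesis (0.497) did not pass. Of 22 tested targets of the stress transcription factor ATF4, 5 rose, 2 fell and 15 did not pass, and 8 rose and 2 fell adjusted over the list alone (median 0.19, camera adjusted p = 0.000495; adjusted p = 0.214 with an estimated correlation). They included the folate enzyme Mthfd2 at 1.45-fold, asparagine synthetase Asns at 1.51-fold and the serine synthesis enzyme Psat1 at 1.42-fold. Asns lies within 20 Mb of Smim30, where all 8 called genes were higher in Mut. Of 34 genes of the lysosome and its proton pump, 5 fell, 1 rose and 28 did not pass, and 9 fell and 1 rose adjusted over the list alone (median -0.07, camera adjusted p = 0.00344; adjusted p = 0.614 with an estimated correlation); the list was lost without WT replicate 3 (0.0999). Tfeb, a regulator of lysosomal genes, fell by 0.35 on the log2 scale and the lysosomal enzyme Naglu by 0.31. Of 23 targets of the antioxidant factor NRF2, 6 fell, 0 rose and 17 did not pass, and 8 fell and 1 rose adjusted over the list alone (median -0.06, camera adjusted p = 0.00215; adjusted p = 0.614 with an estimated correlation). That list was lost without WT replicate 3 (0.0519), and within it the heme oxygenase gene Hmox1 fell by 0.34. Of 55 ribosomal protein genes, which share sequence with many pseudogenes and are uncertain for that reason, 6 rose, 0 fell and 49 did not pass, with 7 rising adjusted over the list alone (median 0.09, camera adjusted p = 0.000261; adjusted p = 0.558 with an estimated correlation). That list was lost without Mut replicate 3 (0.0504).

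Markers of particular peritoneal cell types also moved in Mut, and the share of ribosomal RNA genes was lower in the same 3 libraries, at 0.399 to 1.03% against 1.74 to 2.49% in WT. Of 11 markers of large peritoneal macrophages, 3 fell, 1 rose and 7 did not pass, with the same counts adjusted over the list alone (median -0.18, camera adjusted p = 0.000391; adjusted p = 0.182 with an estimated correlation). Thbs1 fell by 0.69 on the log2 scale, from 255 ± 4.53 to 158 ± 10.3 CPM (n = 3 each, adjusted p = 1.44e-10). Of 7 B cell markers, 1 fell, 0 rose and 6 did not pass, with 3 falling adjusted over the list alone (median -0.50, camera adjusted p = 0.00317; adjusted p = 0.182 with an estimated correlation). The one that fell was Cd22, by 0.51. Of 5 dendritic cell markers, 2 rose, Batf3 and Ccl22, and 3 did not pass, with 2 rising adjusted over the list alone (median 0.30, camera adjusted p = 0.000105; adjusted p = 0.182 with an estimated correlation). Of 9 mesothelial and fibroblast markers, 0 passed in either direction (median -0.01). In all, camera called 13 of 31 lists, 9 higher and 4 lower, and with an estimated correlation it called 0. The directional test fry called 9. Not among them were the lists of type I interferon response, interferon-inducible GTPases, lysosome, NRF2 targets and ribosomal proteins.

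**Figure D2:**
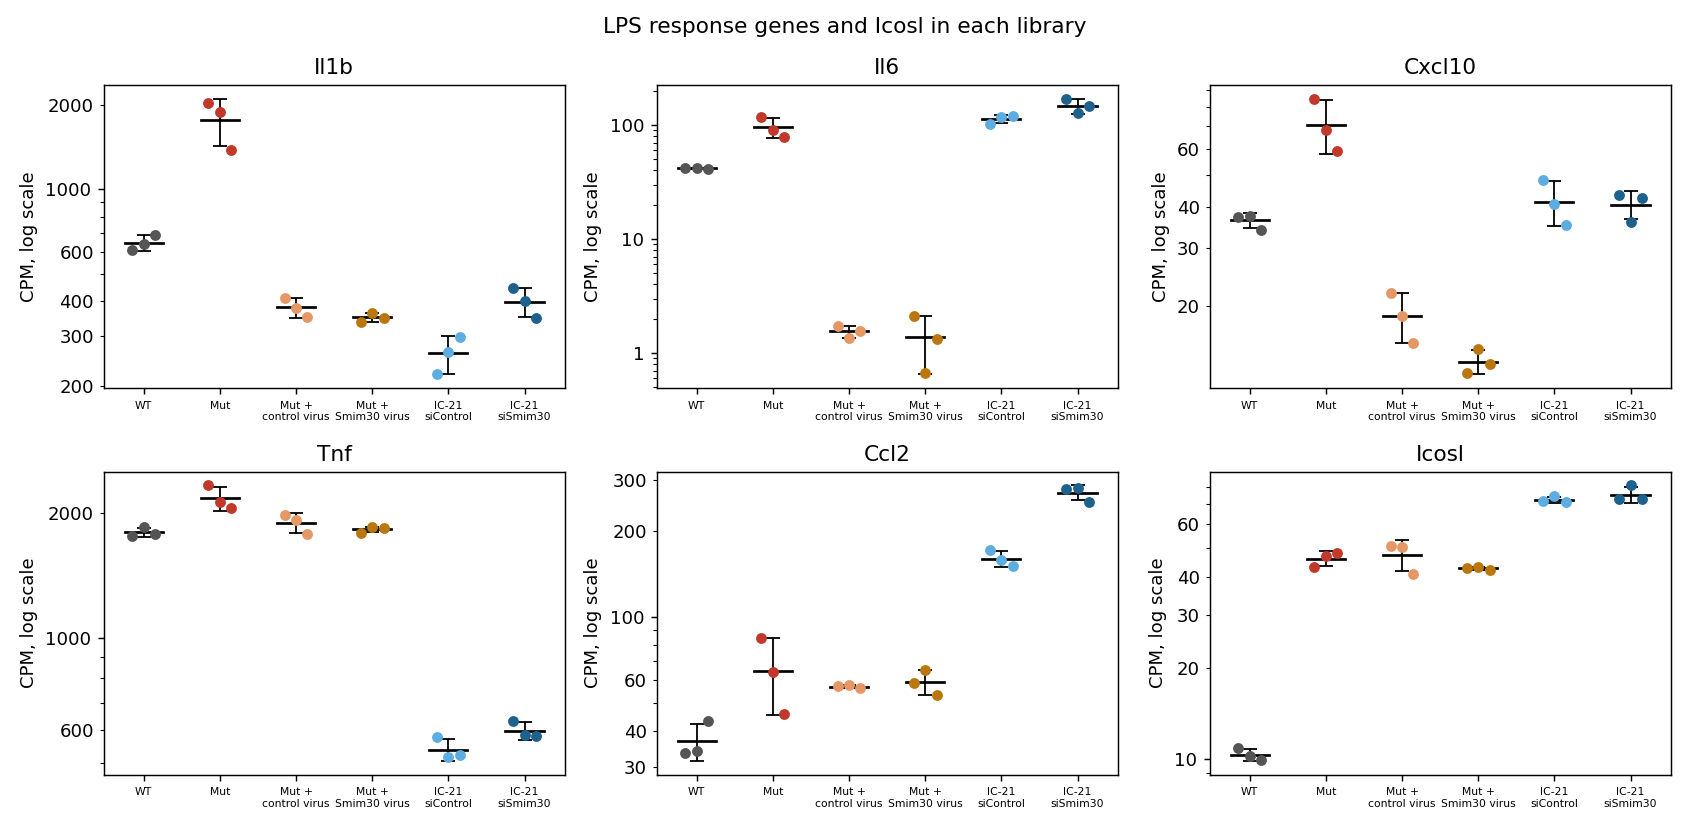
CPM (y axes, log scale) of Il1b, Il6, Cxcl10, Tnf, Ccl2 and Icosl in each of the 18 libraries, by group (x axis); points are libraries, horizontal lines are group means and error bars are 1 SD (n = 3). Icosl lies at 9.91 to 10.8 CPM in the WT libraries and at 41.0 CPM or more in all others.

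The second comparison set Mut macrophages with the Smim30 virus against Mut macrophages with the control virus, to show which transcripts move when Smim30 is overexpressed in the mutant cells. Transcripts of collagens and other fibroblast genes were among the largest falls by the naming rule. Sparc, a matrix-binding glycoprotein, fell by 1.08 on the log2 scale, from 22.1 ± 2.05 CPM in Mut AdCtrl to 10.4 ± 0.980 CPM in Mut AdSmim30 (n = 3 each, SE 0.11, adjusted p = 6.86e-11). The collagen gene Col3a1 fell by 1.24, from 12.6 ± 1.248 to 5.30 ± 0.799 CPM (adjusted p = 1.16e-08), and Col1a2 by 0.91, from 27.6 ± 4.75 to 14.8 ± 0.510 CPM (adjusted p = 6.22e-09). Pdgfra, a growth factor receptor of fibroblasts, fell by 1.296, from 6.68 ± 1.301 to 2.71 ± 0.439 CPM (adjusted p = 1.49e-05). Of 9 tested mesothelial and fibroblast markers, 7 fell, 0 rose and 2 did not pass, with 7 falling adjusted over the list alone (median -1.08, camera adjusted p = 4.04e-42), and the list held with an estimated correlation (adjusted p = 0.0109). Of 12701 genes tested, 181 passed, 74 higher and 107 lower, and all 30 that differed at least 2-fold were lower with the Smim30 virus. The count was 82 without Mut AdCtrl replicate 1, 453 without Mut AdCtrl replicate 3, 106 without Mut AdSmim30 replicate 2 and 66 without Mut AdSmim30 replicate 3, 68 with DESeq2 and 80 in a fit of all 18 libraries. The groups did not overlap for 15.1% of tested genes, against 10% by chance.

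Genes of lipid synthesis rose with the Smim30 virus, in the same libraries in which the fibroblast markers had a median of -1.08. Of 24 tested genes of cholesterol synthesis and uptake, 9 rose, 0 fell and 15 did not pass, with 16 rising adjusted over the list alone (median 0.21, camera adjusted p = 1.06e-24), and the list held with an estimated correlation (adjusted p = 0.0128). Hmgcs1, an early enzyme of cholesterol synthesis, rose 1.18-fold, from 212 ± 3.42 to 250.2 ± 10.6 CPM (n = 3 each, adjusted p = 3.69e-06). Msmo1 and Sqle, enzymes of the same pathway, rose 1.17-fold and 1.21-fold. Of 15 LXR targets and lipid efflux genes, 3 rose, 1 fell and 11 did not pass, and 5 rose and 2 fell adjusted over the list alone (median 0.01, camera adjusted p = 0.00219; adjusted p = 0.307 with an estimated correlation). Scd2, a fatty acid desaturase, rose 1.41-fold from 122 ± 11.9 to 172 ± 2.36 CPM (adjusted p = 9.05e-08), and the lipase gene Lpl rose 1.14-fold from 3737 ± 87.3 to 4276 ± 88.6 CPM (adjusted p = 1.2e-10). Of 26 phagocytic and scavenger receptors, 4 rose, 1 fell and 21 did not pass, and 4 rose and 2 fell adjusted over the list alone (median 0.04, camera adjusted p = 0.0227; adjusted p = 0.307 with an estimated correlation). The integrins Itgam and Itgax rose 1.21-fold and 1.14-fold. That list was lost without Mut AdCtrl replicate 1 (0.0884), Mut AdCtrl replicate 3 (0.0541) or Mut AdSmim30 replicate 3 (0.0826). Of 25 genes of the unfolded protein response, 2 rose, 0 fell and 23 did not pass, with 7 rising adjusted over the list alone (median 0.05, camera adjusted p = 0.00437; adjusted p = 0.307 with an estimated correlation), and it was lost without Mut AdSmim30 replicate 2 (0.0716).

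Some inflammatory lists shifted slightly downward with the Smim30 virus, again beside the lower fibroblast markers (median -1.08), and few of their members passed. Camera did not call the lists of type I interferon response (adjusted p = 0.226), interferon-inducible GTPases (0.889), inflammasome genes (0.218) or TLR4 components (0.218). Of 28 tested cytokines and chemokines, 1 fell, 0 rose and 27 did not pass, with 5 falling adjusted over the list alone (median -0.14, camera adjusted p = 1.85e-05; adjusted p = 0.307 with an estimated correlation). Of 25 NF-kB genes, 3 fell, 0 rose and 22 did not pass, and 6 fell and 1 rose adjusted over the list alone (median -0.06, camera adjusted p = 4.71e-06; adjusted p = 0.307 with an estimated correlation). Of 16 immediate early genes, 1 fell, 0 rose and 15 did not pass, with 5 falling adjusted over the list alone (median -0.11, camera adjusted p = 2.05e-07; adjusted p = 0.307 with an estimated correlation); Egr1 fell by 0.28 (adjusted p = 0.000655), a call lost in the fit of all 18 libraries (0.082, in a range of 2e-06 to 0.082 over all alternatives). Of 21 anti-inflammatory regulators, 1 fell, 0 rose and 20 did not pass, with 1 falling adjusted over the list alone (median -0.06, camera adjusted p = 0.00225; adjusted p = 0.307 with an estimated correlation); it was the phosphatase gene Dusp1, by 0.25. Of 22 NRF2 targets, 2 fell, 0 rose and 20 did not pass, and 5 fell and 1 rose adjusted over the list alone (median -0.03, camera adjusted p = 0.00945; adjusted p = 0.307 with an estimated correlation), lost without Mut AdCtrl replicate 2 (0.0676). Of 16 MHC class I genes, members of a multigene family and uncertain for that reason, 3 fell, 0 rose and 13 did not pass, with 6 falling adjusted over the list alone (median -0.03, camera adjusted p = 0.0159; adjusted p = 0.316 with an estimated correlation). That list was lost without Mut AdCtrl replicate 1 (0.13), Mut AdSmim30 replicate 1 (0.076) or Mut AdSmim30 replicate 3 (0.0749). In all, camera called 11 of 31 lists, 4 higher and 7 lower, 2 of them with an estimated correlation, and fry called 3. Of the lists that camera called, fry called only those of cholesterol synthesis and of mesothelial and fibroblast markers.

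Of the cytokines named in every comparison, only Cxcl10 passed with the Smim30 virus, at 18.7 ± 3.17 CPM in Mut AdCtrl and 13.7 ± 1.15 CPM in Mut AdSmim30 (n = 3 each; log2 fold change -0.46, SE 0.11, adjusted p = 0.0122). Its call was lost without Mut AdCtrl replicate 1 (0.341), Mut AdCtrl replicate 2 (0.0632), Mut AdSmim30 replicate 1 (0.108) or Mut AdSmim30 replicate 3 (0.131), with DESeq2 (0.155) and in the fit of all 18 libraries (0.484), in a range of 0.000102 to 0.484. Tnf was at 1897 ± 103 and 1834 ± 31.9 CPM and did not pass (adjusted p = 0.628), though it did without Mut AdCtrl replicate 3 (0.0026, in a range of 0.0026 to 1 over all alternatives). Il1b was at 381 ± 30.4 and 351 ± 14.2 CPM (adjusted p = 0.562) and Il6 at 1.55 ± 0.174 and 1.38 ± 0.724 CPM (adjusted p = 0.902). Nos2 was at 1.77 ± 0.0821 and 1.87 ± 0.739 CPM (adjusted p = 0.966). The size of the overexpression in these cells is not known from the gene-level counts.

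The third comparison set IC-21 cells with Smim30 siRNA against control siRNA, to show which transcripts move when Smim30 is lowered in a macrophage line. Chemokines and colony-stimulating factors were among the largest rises by the naming rule. Ccl2, which recruits monocytes, rose 1.73-fold, from 159 ± 9.56 CPM with siCtrl to 274 ± 17.1 CPM with siSmim30 (n = 3 each; log2 fold change 0.79, SE 0.04, adjusted p = 7.41e-18), and its relative Ccl7 rose 1.81-fold, from 40.8 ± 0.796 to 73.7 ± 5.84 CPM (adjusted p = 7.84e-15). Csf2, which encodes the growth factor GM-CSF, rose 1.95-fold, from 6.69 ± 1.05 to 12.9 ± 1.96 CPM (adjusted p = 3.16e-05). Csf3, which encodes the growth factor G-CSF, rose 2.28-fold, from 21.8 ± 4.49 to 49.7 ± 8.48 CPM (adjusted p = 0.00518), a call lost without siSmim30 replicate 2 (0.0506) and with replicate number as a block (0.125, in a range of 3.66e-36 to 0.125 over all alternatives). The growth factor gene Pdgfb rose 1.54-fold and the collagenase gene Mmp13 1.54-fold. The phosphatase gene Ptpn4 fell by 0.42 on the log2 scale, from 145 ± 2.53 to 109 ± 4.55 CPM (adjusted p = 7.64e-10), and Card19 fell by 0.41. Of 13576 genes tested, 472 passed, 324 higher and 148 lower with siSmim30 (68.6% higher), and 5 differed at least 2-fold (3 higher, 2 lower). Scaled to library totals alone, 495 passed, 54.3% of them higher. The count was 309 without siCtrl replicate 2, 291 with DESeq2 and 281 in a fit of all 18 libraries. The groups did not overlap for 19% of tested genes, against 10% by chance.

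Of 22 tested LPS-induced cytokines and chemokines, 11 rose with siSmim30, 0 fell and 11 did not pass, with 16 rising adjusted over the list alone (median 0.37, camera adjusted p = 6.95e-38; adjusted p = 0.0511 with an estimated correlation). Ccl4 rose 1.29-fold (adjusted p = 1.41e-12) and Ccl3 rose by 0.32 on the log2 scale (adjusted p = 8.32e-11). Tnf rose 1.12-fold, from 538 ± 30.7 to 604 ± 30.2 CPM (n = 3 each, adjusted p = 0.00307), a call lost without siSmim30 replicate 1 (0.0547, in a range of 1.91e-05 to 0.0547). Il6 was at 114 ± 9.82 and 150 ± 22.3 CPM (adjusted p = 0.349), Il1b at 260 ± 40.6 and 402 ± 49.1 CPM (adjusted p = 0.192), and Cxcl10 at 41.2 ± 6.27 and 41.0 ± 4.02 CPM (adjusted p = 0.999), and these did not pass. Nos2 was below the filter on low counts. Of 25 NF-kB genes, 6 rose, 0 fell and 19 did not pass, with 8 rising adjusted over the list alone (median 0.08, camera adjusted p = 2.51e-07; adjusted p = 0.0711 with an estimated correlation). Nfkbiz rose 1.16-fold and Zc3h12a, an RNase that degrades cytokine transcripts, 1.18-fold. Of 19 anti-inflammatory regulators, 7 rose, 0 fell and 12 did not pass, with 8 rising adjusted over the list alone (median 0.24, camera adjusted p = 2.04e-12), and the list held with an estimated correlation (adjusted p = 0.0352). The interleukin-1 receptor antagonist Il1rn rose 1.34-fold, Socs3 1.44-fold and Dusp1 1.31-fold. Of 14 immediate early genes, 5 rose, 0 fell and 9 did not pass, with 6 rising adjusted over the list alone (median 0.23, camera adjusted p = 1.76e-07; adjusted p = 0.0556 with an estimated correlation). Of 4 alternative activation markers, 2 rose, Il4ra and Stab1, and 2 did not pass, with 2 rising adjusted over the list alone (median 0.31, camera adjusted p = 0.00115; adjusted p = 0.0824 with an estimated correlation).

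Glycolysis and cell cycle genes were higher with siSmim30. Of 25 tested genes of glycolysis and HIF-1 metabolic targets, 8 rose, 0 fell and 17 did not pass, and 13 rose and 1 fell adjusted over the list alone (median 0.10, camera adjusted p = 1.75e-09; adjusted p = 0.0511 with an estimated correlation). Bnip3, a mitophagy receptor induced by HIF-1, rose 1.51-fold, and the glycolytic enzymes Tpi1 and Pgk1 rose 1.21-fold and 1.15-fold. Of 37 cell cycle genes, 9 rose, 0 fell and 28 did not pass, with 16 rising adjusted over the list alone (median 0.11, camera adjusted p = 1.97e-10; adjusted p = 0.0511 with an estimated correlation). E2f1 rose 1.13-fold. Of 21 ATF4 targets, 2 rose, 0 fell and 19 did not pass, with 2 rising adjusted over the list alone (median 0.04, camera adjusted p = 0.0461; adjusted p = 0.4 with an estimated correlation), lost without siCtrl replicate 3 (0.266), siSmim30 replicate 1 (0.103) or siSmim30 replicate 3 (0.106). Of 5 neutrophil markers, 1 rose, Lcn2 at 1.46-fold, and 4 did not pass, with 1 rising adjusted over the list alone (median 0.13, camera adjusted p = 0.0322; adjusted p = 0.175 with an estimated correlation), lost without siCtrl replicate 3 (0.0919) or siSmim30 replicate 1 (0.0983).

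A few lists were lower with siSmim30. Of 21 tested genes of the type I interferon response, 1 fell, 0 rose and 20 did not pass, with 3 falling adjusted over the list alone (median -0.08, camera adjusted p = 0.0322; adjusted p = 0.154 with an estimated correlation), lost without siCtrl replicate 3 (0.184), siSmim30 replicate 1 (0.0575) or siSmim30 replicate 2 (0.0558). Of 14 MHC class I genes, a multigene family and uncertain for that reason, 1 fell, 0 rose and 13 did not pass, with 5 falling adjusted over the list alone (median -0.07, camera adjusted p = 0.018; adjusted p = 0.146 with an estimated correlation), lost without siCtrl replicate 3 (0.0815). Of 23 genes of cholesterol synthesis and uptake, 0 passed in either direction, over all genes or adjusted over the list alone (median -0.06, camera adjusted p = 0.018; adjusted p = 0.527 with an estimated correlation), lost without siCtrl replicate 3 (0.375), siSmim30 replicate 1 (0.165) or siSmim30 replicate 3 (0.0679). In all, camera called 12 of 27 lists, 9 higher and 3 lower, 1 of them with an estimated correlation, and fry called 10. The lists of type I interferon response, ATF4 targets and cholesterol synthesis did not pass with fry.

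**Figure D3:**
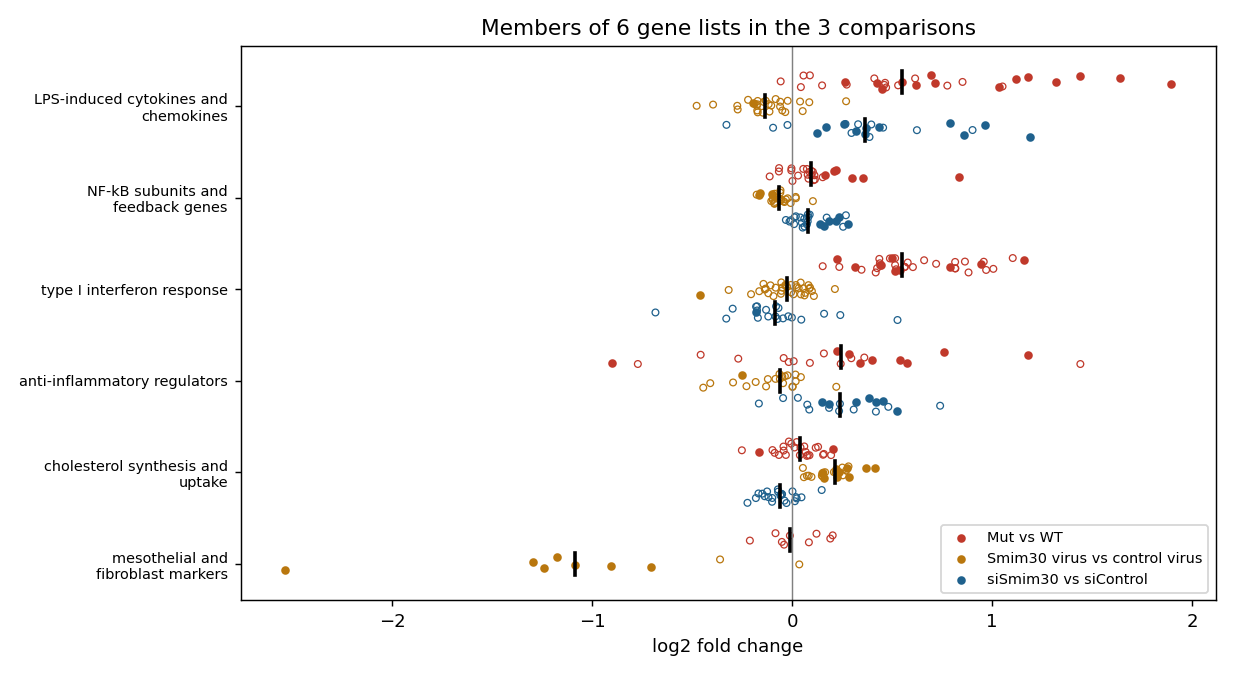
Log2 fold change (x axis) of each tested member of 6 gene lists (y axis) in the 3 comparisons; filled points have an adjusted p under 0.05, open points do not, and vertical bars are list medians. The cytokine list has medians of 0.55 in Mut against WT, -0.14 with the Smim30 virus and 0.37 with the siRNA.

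The mutation and the knockdown raised an overlapping set of genes. Of 11404 genes tested in both, 65 were higher in Mut and with siSmim30, against 11.2 for independent lists (Fisher's exact test, two-sided, adjusted p = 4.99e-31, over 12 such tests), and 10 were lower in both, against 3.8 (adjusted p = 0.0116). Fisher's test takes genes as independent draws, which they are not, and the overlaps were not set against regrouped libraries. The shared rises with the largest changes included Csf2 (log2 fold change 1.90 with the mutation and 0.97 with the siRNA), Pdgfb (0.77 and 0.63), Mmp13 (0.59 and 0.62) and Socs3 (0.57 and 0.52). The call of Csf2 in Mut was lost without WT replicate 3 (adjusted p = 0.0602) or Mut replicate 1 (0.0588), in a range of 0.000744 to 0.0602 over the alternatives that gave an adjusted p. DESeq2 gave none for Csf2 in either comparison, as its filter on mean counts set the gene aside. The mean normalized count was 12.1 in Mut against WT (threshold 33.9) and 83.5 with the siRNA (threshold 172). Another 7 genes were higher in Mut and lower with siSmim30, against 5.22 (adjusted p = 0.492), and 14 the reverse, against 8.15 (adjusted p = 0.0778). The last of these passed with DESeq2 (12 genes, adjusted p = 0.00348) and with replicate number as a block (16 genes, 0.0199). Across all genes, which are not independent replicates, the fold changes were nearly unrelated (Pearson's r = 0.082, Spearman's rho = 0.057). Without WT replicate 2 r was 0.053, in a range of 0.053 to 0.107 with a library left out. As large an r came from 4 of 100 splits of the libraries, the real one included, a share of 0.04, or 0.12 adjusted over the 3 correlations. The interaction itself, the mutation effect minus the siRNA effect in one model of 12 libraries, passed for 372 of 14804 genes, 185 higher and 187 lower, and for 571 without Mut replicate 3. Its smallest adjusted p-values were those of Icosl (2.09, adjusted p = 2.55e-19) and Spp1, the secreted protein osteopontin (0.96, adjusted p = 1.03e-13). Those of Ago2, of the RNA silencing complex (-0.78, adjusted p = 8.67e-13), Lpl (0.76, adjusted p = 1.24e-11) and the protease inhibitor gene Slpi (-0.82, adjusted p = 5.63e-11) followed.

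**Figure D4:**
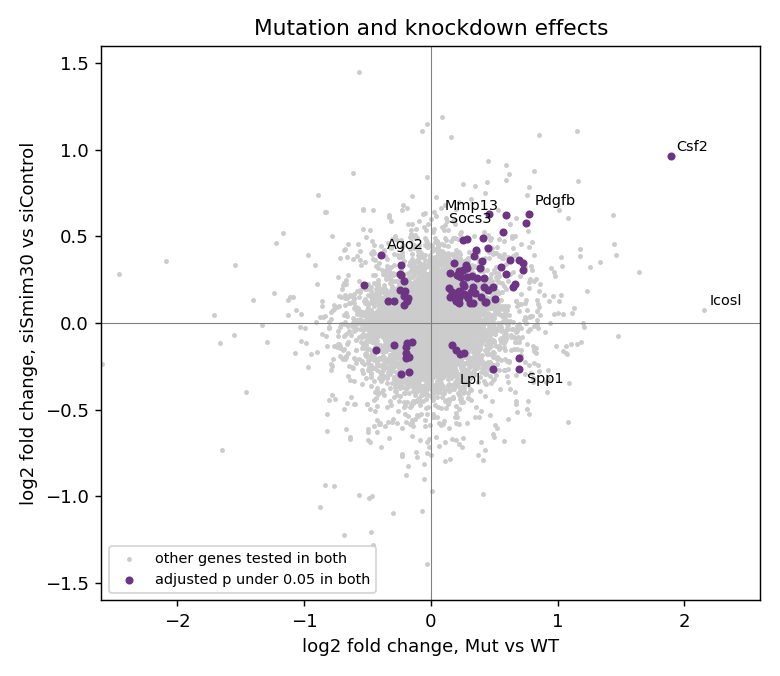
Log2 fold change in Mut against WT (x axis) and with siSmim30 against siCtrl (y axis) for 11404 genes tested in both comparisons, 2 of which lie outside the axes; purple points are the 96 genes with an adjusted p under 0.05 in both, grey points all others. Of the 96, 75 moved the same way, and Icosl lies at 2.16 on the x axis and 0.07 on the y axis.

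Genes changed with the mutation were not enriched among genes that the Smim30 virus moved the other way. Of 12037 genes tested in both comparisons, 16 were higher in Mut and higher with the Smim30 virus, against 2.75 for independent lists (Fisher's exact test, two-sided, adjusted p = 5.75e-08), and 12 were lower in both, against 2.8 (adjusted p = 8.92e-05). Lpl was among the genes higher in both. In the opposing directions, 3 genes were higher in Mut and lower with the virus, Cxcl10 among them, against 3.91 (adjusted p = 1), and 3 the reverse, against 1.97 (adjusted p = 0.54). The fold changes had r = 0.046 and rho = 0.07 across genes, with as large an r in 34 of 100 splits (adjusted share 0.51). That r was 0.029 without WT replicate 2 or Mut AdCtrl replicate 3 and 0.027 without Mut AdSmim30 replicate 2, in a range of 0.027 to 0.067 with a library left out. The sum of the virus effect and the mutation effect, which is 0 where the virus exactly reverses the mutation, differed from 0 for 702 of 13422 genes, 374 above and 328 below. The 5 genes with the smallest adjusted p-values were Icosl (2.02, adjusted p = 9.51e-16), Lpl (0.68, adjusted p = 9.31e-13), Spp1 (0.88, adjusted p = 1.79e-11), Anxa1 (0.57, adjusted p = 7.54e-11) and Fam53c (0.87, adjusted p = 7.76e-11). The size of the Smim30 overexpression is not known from the gene-level counts. Both viral groups had a longer culture than the groups of the mutation comparison and belonged to another part of the series. Many cytokines were lower in Mut AdCtrl than in Mut. Against Mut, 22 of 29 tested cytokines and chemokines fell there, 3 rose and 4 did not pass, with 23 falling and 3 rising adjusted over the list alone (median -1.89, camera adjusted p = 3.91e-14; adjusted p = 0.267 with an estimated correlation). Il6 went from 97.5 to 1.53 CPM, while Tnf fell by only 0.23 on the log2 scale. Other lists went both ways, with 14 of 25 NF-kB genes higher and 10 lower (median 0.14), and 9 of 21 anti-inflammatory regulators higher and 9 lower. Of 16 immediate early genes, 10 rose, 4 fell and 2 did not pass, with 11 rising and 4 falling adjusted over the list alone (median 0.67, camera adjusted p = 0.00413; adjusted p = 0.394 with an estimated correlation). Between the virus and the siRNA, 5 of 11556 genes were higher with the first and lower with the second, against 0.85 (adjusted p = 0.0048), among them Lpl and Spp1. Another 5 were higher with both, against 1.85 (adjusted p = 0.0754), the virus lowered and the siRNA raised 3, against 1.74 (adjusted p = 0.38), and 0 were lower in both, against 0.8 (adjusted p = 1). Higher with both passed with replicate number as a block (12 genes, adjusted p = 0.00026). Lower with the virus and higher with the siRNA passed with the block (11 genes, 0.000223) and with DESeq2 (2 genes, 0.0464). Their fold changes had r = -0.003 and rho = -0.002, with as large an r in 93 of 100 splits (adjusted share 0.93).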

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

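The regrouping of libraries for the interaction was planned before the data were examined, and the tests on Icosl were chosen only after its result was seen. The mutation effect and the siRNA effect differed for 372 of 14804 genes. In 50 drawn regroupings of the 12 libraries, only 1, the real one, gave as many, and the highest other gave 162. Draws that kept only the real Mut and WT groups gave 150 to 162, and those that kept only the real siRNA groups gave 3 to 76. Draws that regrouped both gave at most 11. Regrouped sets mix real groups and so vary more, which by itself lowers their counts. Spp1 rose by 0.70 on the log2 scale in Mut and fell by 0.26 with siSmim30, a difference of 0.962 (SE 0.07). Lpl did the same, with 0.49 and -0.27 and a difference of 0.756 (SE 0.07). Ago2 fell by 0.39 in Mut and was higher by 0.39 with siSmim30, a difference of -0.782 (SE 0.06). Slpi fell by 0.72 in Mut and did not pass with siSmim30, a difference of -0.821 (SE 0.08). Cell type and kind of perturbation differ together between these comparisons, primary macrophages with a mutated gene against a cell line with less of the RNA.

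Icosl had the smallest adjusted p of the difference, which was 2.089, being 4.46-fold higher in Mut (log2 fold change 2.16) and not shown to differ with siSmim30 (0.07, 95% interval -0.04 to 0.19). A variant near Smim30 that acts on Icosl in cis is excluded by position, since Icosl (ENSMUSG00000000732.9) lies on chromosome 10, from 78069302 to 78083913 in GRCm38, and Smim30 on chromosome 6. A linked variant that acts in trans was not tested and stays open. Within 20 Mb of Smim30, 8 of 94 tested genes were called, against 780 of 12406 elsewhere (Fisher's exact test, two-sided, p = 0.389). All 8 were higher in Mut, against 452 of the 780 elsewhere (Fisher's exact test, two-sided, p = 0.0238). That comparison of directions was chosen after the genes were seen. Among the 8 were St7 by 0.76, Asns by 0.59, Gpr85 by 0.48 and Irf5, a member of the list of TLR4 components, by 0.18. Gpr85 ends at 13839942, close to the start of Smim30. An unlinked genetic difference between the mice and a loss of Smim30 function cannot be told apart here, because gene-level counts do not show how far the virus raised the coding RNA of Smim30. With the Smim30 virus Icosl moved by -0.146 (95% interval -0.277 to -0.015, adjusted p = 0.42), and the sum of mutation and virus effects was 2.017 (1.774 to 2.26). The level in each group was 10.3 CPM in WT, 46.2 CPM in Mut, 47.5 CPM in Mut AdCtrl, 43.0 CPM in Mut AdSmim30, 72.4 CPM with siCtrl and 75.4 CPM with siSmim30. WT was thus the only group below 43.0 CPM, and IC-21 cells with siCtrl, whose Smim30 was not targeted, were high. A genetic difference between the WT and Mut mice other than the mutation could also bear on other genes called between them, which was not tested.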

How the results depend on the processing

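Each main result was set against each alternative setting. Of these pairs, 235 were labelled unchanged, 20 moved, 14 weakened, 5 strengthened and 0 reversed, and the causes of the shifts were not tested. A count within a set factor of the main count was labelled unchanged, such as 534 against 788 in Mut against WT without WT replicate 2. Counts could not be labelled reversed. Correlations were unchanged within the SD of the other splits. Among other results, such as single genes and lists, 11475 pairs were unchanged, 38 moved, 789 weakened and 160 strengthened. The count in Mut against WT was 1279 in a fit of all 18 libraries and 469 to 957 with a library left out. With the Smim30 virus it was 68 with DESeq2, 80 in all 18 libraries and 66 to 453 with a library left out. With siSmim30 it was 291 with DESeq2, 281 in all 18 libraries and 309 to 422 with a library left out. The interaction count was 267 to 571 with a library left out. The Smim30 virus effect on Smim30 was 0.275 with DESeq2 and in all 18 libraries, where the call was lost, and 0.245 to 0.307 with a library left out. The control virus effect on Smim30 (-0.19) lost its call with no composition factor (-0.154), no filter (-0.168), DESeq2 (-0.191), limma-voom (-0.185), a replicate block (-0.18) and GC offsets (-0.142), and ran from -0.266 to -0.133 with a library left out. It was also lost without Mut replicate 2 (adjusted p = 0.211), Mut replicate 3 (0.141), Mut AdCtrl replicate 2 (0.12) or Mut AdCtrl replicate 3 (0.0782).

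The correlation of mutation and siRNA effects was 0.131 among genes with log2 CPM of at least 4, and that of virus and siRNA effects ran from -0.034 to 0.012 with a library left out. Genes lower in Mut and higher with siSmim30 numbered 12 with DESeq2 (adjusted p = 0.00348) and 16 with a replicate block (0.0199). Genes higher with virus and siRNA numbered 12 with the block (0.00026), and those lower with virus and higher with siRNA numbered 2 with DESeq2 (0.0464) and 11 with the block (0.000223). The block treats equal replicate numbers as pairs, and no comparison had every sample correlate best with its own number. With an estimated correlation, camera called 0 lists in Mut, 2 with the Smim30 virus, 1 with siSmim30 and 0 with the control virus, and this gave the highest adjusted p of every called list except interferon genes with siSmim30. The test fry called 3 lists with the Smim30 virus and 28 with the control virus. DESeq2 gave no adjusted p for Smim30 with the siRNA, as its filter set the gene aside (unadjusted p = 1.31e-09 by DESeq2's Wald test on counts).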

Other observations

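The split counts of the comparisons, the splits of correlations, and the tests of ribosomal RNA, GC content, cell markers and other cell types were chosen only after the results were seen, while those on further fibroblast genes were written down after the fall of fibroblast markers was seen and before these genes were examined. Mut cells with control virus against Mut cells without virus gave more called genes than any other comparison. Virus, time in culture and part of the series coincided there, so a batch cannot be told apart from them. Of 12798 genes, 6862 passed, 3472 higher and 3390 lower in Mut AdCtrl. Il6 fell by 5.96 on the log2 scale (SE 0.28, adjusted p = 4.72e-06), from 97.5 CPM in Mut to 1.53 CPM in Mut AdCtrl. Cxcl3 fell by 5.66 (SE 0.05), from 1173 to 23.1 CPM, Il1b by 2.24 and Cxcl10 by 1.93, while Tnf fell by only 0.23. The costimulatory receptor gene Cd28 rose by 5.19, from 1.44 to 52.5 CPM, and the immediate early gene Egr1 by 4.25, from 3.95 to 77.9 CPM. Of 36 interferon genes, 33 fell (median -1.85, camera adjusted p = 4.67e-14; adjusted p = 0.394 with an estimated correlation), and of 25 cholesterol genes 23 fell (median -1.21, camera adjusted p = 4.54e-19; adjusted p = 0.247 with an estimated correlation). Of 34 lysosomal genes, 27 rose and 3 fell (median 0.58, camera adjusted p = 1.17e-10; adjusted p = 0.247 with an estimated correlation). All 9 fibroblast markers fell (median -1.20, camera adjusted p = 1.09e-07; adjusted p = 0.247 with an estimated correlation).

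The lower fibroblast transcripts with the Smim30 virus may reflect fewer fibroblasts in those wells. Further fibroblast genes that do not encode matrix had a median of -0.517 (95% interval -1.229 to -0.035, n = 10 genes), with 9 of 10 below 0 and 3 called lower. This is a smaller fall than the median of -1.08 of the fixed list, where fewer such cells would give about the same, and single genes ran from -1.417 to 0.192. The smaller fall cannot decide, since the set was limited by level in IC-21 cells and not in primary macrophages. It may hold genes that the macrophages express, such as Fgfr1, at 112.7 CPM in Mut AdCtrl and moved by -0.076. An effect on matrix genes alone is not settled, since further matrix genes differed from these by -0.413 (95% interval -1.016 to 0.328, n = 24 genes). Markers of 4 other cell types had a median of -0.036 (95% interval -0.137 to 0.267, n = 15 genes). Unlike the further fibroblast genes, these markers were not limited to genes under 1 CPM in IC-21 control cells. Some neutrophil markers, such as Lcn2, passed the filter on low counts in IC-21, a macrophage line. The set therefore cannot decide whether the control virus wells held fewer macrophages. Col1a1 fell from 28.1 to 17.2 CPM and was among the most abundant of these transcripts.

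The higher inflammatory genes in Mut came with a lower share of ribosomal RNA genes, and a technical difference between the libraries could underlie both. After offsets for GC content and length the cytokine median was 0.498 (0.551 without them), and the same 14 of 29 members were higher. Leaving out the ribosomal RNA genes gave 0.551 again. This cannot decide the role of their share of the counts, since the TMM scaling already allows for such a share. The 95th percentile of the shift in fold change over all genes was only 1e-04. How RNA was prepared also stays open. A lower share of large peritoneal macrophages stays open, since their markers had a median of -0.181 (95% interval -0.66 to -0.006, n = 11 genes), with 9 of 11 below 0, 3 called lower and 1 higher. In the same libraries 5 of 5 dendritic cell markers were above 0 (median 0.30, camera adjusted p = 0.000105; adjusted p = 0.182 with an estimated correlation), among them Ccl22, which the cytokine list also holds. B cell markers had a median of -0.50 (camera adjusted p = 0.00317; adjusted p = 0.182 with an estimated correlation).

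Splits of 6 libraries are too few for a share under 0.05, and only 1 of 10, the real one, gave as many genes in each comparison. The real and highest other counts were 788 and 11 in Mut against WT, 181 and 11 with the Smim30 virus, 472 and 1 with siSmim30, and 6862 and 0 with the control virus. For the sum of mutation and virus effects, 1 of 50 drawn splits, the real one, reached 702, and the highest other gave 461. Draws that kept only the real Mut and WT groups gave 347 to 461, those that kept only the real virus groups 9 to 20, and those that regrouped both at most 8. For the correlations, 34 of 100 splits reached 0.046 for mutation and virus (highest other 0.162), 4 reached 0.082 for mutation and siRNA (0.116), and 93 reached 0.003 in size for virus and siRNA (0.039).

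G530011O06Rik, chosen after its values were seen, was at 8.85 ± 1.13 CPM in WT and at 0.232 to 1.09 CPM on average in the other 5 groups (n = 3 each). Like Icosl, it set WT apart from all other groups, IC-21 cells with siCtrl included. Whether a genetic difference of the WT mice other than the mutation lies behind either gene was not tested.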
